A study of Mus musculus with 67 samples.

How the data were processed

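RNA was sequenced from liver pieces of 40 SPF and 27 germ-free (GF) C57BL/6 mouse libraries, grouped by housing, purified diet (LF, HF, FFHC or FFVHC) and time on the diet (8 or 24 weeks) into 16 groups of 3 to 6, as the labels give them. The deposited table holds raw read counts per gene symbol for 55291 genes in 67 libraries, not normalised by the authors. Per the submitters' processing notes, the tools named were FastQC, STAR 2.4.2a, featureCounts of Subread 1.4.6-p1, edgeR 3.22.5 and limma 3.38.3, with the mouse build mm10. The strand setting and the annotation release behind the counts are not given in the sources used here. The values were checked to be whole numbers, as counts are, and 20809 genes had no count in any library. Symbols were set beside GENCODE M21 (GRCm38) for positions, and 53292 of them matched a symbol there.

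Total counts per library lay between 24264151 and 29911647 in 62 libraries and between 52262083 and 55332994 in 5. In those 5, between 72.6 and 76.2% of the counts from 1 to 10 were even, against 35.4 to 39.0% in the other 62. At the lowest total, a gene at 5 CPM (counts scaled to the library total) rested on 121 counts, a counting error of 9.1%. A count of 0 was read as up to 3 counts, which is 0.124 CPM in the library of the lowest total, and this floor covers counting error only. Between the 118 pairs of libraries of 1 group, chi-square per degree of freedom lay between 21.2 and 907.6 over genes with at least 20 counts, so the spread between libraries was far above counting error. Mitochondrially encoded genes took 3.37 to 6.58% of the counts.

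The main test was edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM factors (0.72 to 1.31), a filter on low counts by group size (filterByExpr, which kept 15840 genes), 1 mean for each of the 16 groups, and quasi-likelihood F-tests with 51 residual degrees of freedom. In each of 35 comparisons p-values were adjusted by Benjamini and Hochberg over the genes tested, and an adjusted p under 0.05 counts as changed. The comparisons were each diet against LF, the interaction of diet and housing, SPF against GF mice within a diet, FFHC against HF and FFVHC against FFHC in SPF mice, 24 against 8 weeks over the mean of the 4 diets, and the interaction of diet and time in SPF mice. Fold changes are on the log2 scale with the standard error (SE) recovered from the F statistic, and group levels are mean CPM with the standard deviation (SD), on totals scaled by the TMM factors. Fits, comparisons, lists and alternatives were set before the data were examined, except for 3 alternatives named as chosen after seeing the data.

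Of 35 gene lists fixed at that point, from textbook knowledge of liver metabolism, inflammation, matrix, cell types and their markers, 33 were tested as sets. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. The estimated correlation ends nearly every call: 411 of the 1155 list tests passed with the preset and 4 with the estimate. For each list the members that rose or fell were also counted with p adjusted over the list alone. Genes are named by a rule set before the data were examined. It takes the 6 widest rises and 6 widest falls of each comparison among called genes of at least 2 CPM whose groups do not overlap, up to 4 members of a described list with the smallest p, a list of 28 genes always shown, and sex-linked genes. A gene outside the rule is said to have been chosen after its values were seen. Gene models without a proper symbol were left out of the names.

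The alternatives were DESeq2's size factors in place of TMM, no filter on low counts, DESeq2 1.42.0 in place of edgeR, fits on the compared groups only, and leaving out each library in turn. After seeing the data, the counts of the 5 deep libraries were divided by 2, a set of 8 libraries was entered as a covariate, and, for SPF against GF mice, the log2 ratio of Dbp to Arntl. Each count of genes was set beside counts from up to 100 other splits of the same libraries. The code was tested on simulated data in which 50 genes each were changed 1.5-, 2-, 4- and 8-fold between the groups of 3 comparisons. For 6 SPF HF and 6 LF libraries edgeR found 22, 60, 94 and 100.0% with 6 false calls, and for 3 GF HF and 5 LF libraries 8, 50, 84 and 94% with 8. The rates hold for simulated data only. Sequence reads were not used here, and no library was left out of the reported values.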

Results

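Gene counts were measured by RNA sequencing in 67 liver libraries of C57BL/6 mice. The series concerns a fast-food diet model of nonalcoholic fatty liver disease and the part that gut microbes play in it. 40 libraries came from SPF mice and 27 from germ-free (GF) mice, fed 1 of 4 purified diets coded LF, HF, FFHC and FFVHC for 8 or 24 weeks. Each SPF group held 4 libraries at 8 weeks and 6 at 24 weeks. Each GF group held 3 libraries at 8 weeks, and at 24 weeks the GF groups held 5 (LF), 3 (HF), 3 (FFHC) and 4 (FFVHC). Total counts lay between 24264151 and 29911647 in 62 libraries and between 52262083 and 55332994 in the other 5. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these libraries. The Y-linked gene Ddx3y stood between 65.6 and 165.1 CPM (counts scaled to the library total) and Xist, the RNA of the inactive X chromosome, at 0.39 CPM or less in all 67 libraries.

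Some measured features cut across the groups. In 8 libraries Scand1 lay between 11.1 and 20.5 CPM and the histone gene H2aj between 17.2 and 23.6 CPM. The 8 were spread over 5 groups, with 2 of 6 SPF HF, 1 of 6 SPF FFVHC, 3 of 5 GF LF and 1 of 3 GF FFHC libraries of 24 weeks and 1 of 3 GF FFVHC libraries of 8 weeks. In the other 59 libraries Scand1 lay between 0.378 and 3.87 CPM and H2aj between 2.77 and 7.94 CPM. Nnt, which encodes a mitochondrial transhydrogenase (chromosome 13, 119335448 to 119408997, GRCm38), lay between 37.2 and 74.1 CPM in the 40 SPF libraries and between 114.6 and 197.9 CPM in the 15 GF libraries of 24 weeks. Of the 12 GF libraries of 8 weeks, 5 lay between 154.2 and 196.9 CPM and 7 between 54.8 and 76.0 CPM. Scand1, H2aj and Nnt as a check of the libraries were chosen after their values were seen. The output of the liver clock also differed, and the labels give no hour of harvest. At 8 weeks the log2 ratio of Dbp, a clock-driven transcription factor chosen after its values were seen, to the clock gene Arntl lay between 4.5 and 6.27 in SPF and between -0.71 and -0.34 in GF libraries on LF. Nor did the ranges overlap on FFHC at 8 weeks (2.58 or more against 1.88 or less) or on LF (3.39 against 2.7) and FFHC (4.24 against 2.92) at 24 weeks, so housing and clock phase are confounded on these 2 diets. On HF and FFVHC they overlapped.

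**Figure D1:**
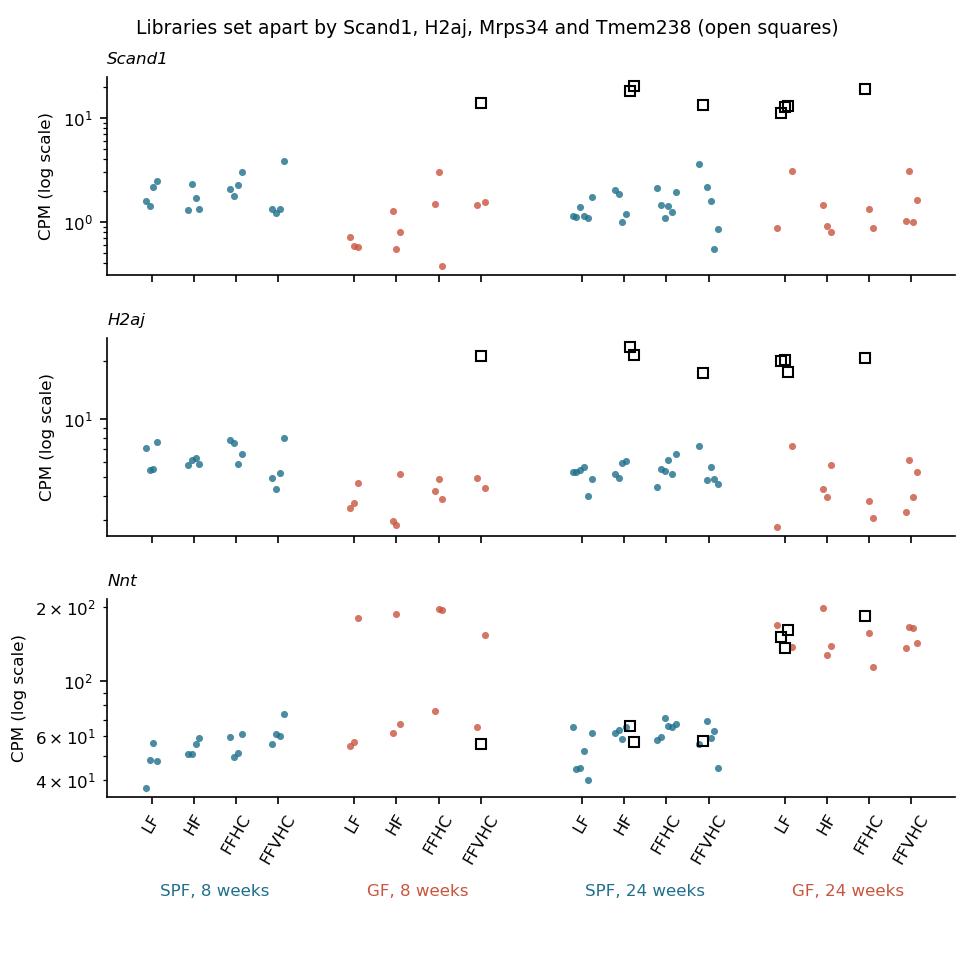
CPM (log scale) of Scand1, H2aj and Nnt in each of the 67 libraries, by group, with open squares for the 8 libraries that stand apart in Scand1. Scand1 lies at 11.1 CPM or more in those 8 and at 3.87 CPM or less in the other 59, and Nnt lies at 74.1 CPM or less in every SPF library.

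The first question was how each diet differed from LF in SPF mice after 8 weeks (n = 4 per group). In FFVHC livers some genes of lipid-laden macrophages, matrix and dividing cells rose, and these calls rest on few libraries. Gpnmb, a lysosomal glycoprotein of such macrophages (chromosome 6, 49036546 to 49070929, GRCm38), stood at 12 ± 14.6 CPM (SD) against 0.201 ± 0.190 CPM in LF. Its log2 fold change was 5.83 ± 1.36 (SE; adjusted p = 0.0187). The macrophage elastase Mmp12 stood at 25.7 ± 30.3 against 0.521 ± 0.576 CPM and the glutathione transferase Gsta1, whose reads paralogs may share, at 12.7 ± 8.91 against 0.348 ± 0.270 CPM. Among lipid genes the hormone gene Fgf21 rose 7.99-fold (adjusted p = 0.0387) and the lipid droplet gene Cidec 8.92-fold. The cholesterol synthesis genes Fdps, at 5.06 ± 2.37 against 17.3 ± 7.17 CPM, Nsdhl and Tm7sf2 fell, with log2 fold changes of -1.78, -1.35 and -0.92. Of 16 cell cycle genes 8 rose (15 adjusted over the list alone), among them the cyclin gene Ccnb1 (log2 fold change 4.90 ± 0.93), Cdc20 (3.98 ± 0.80), Ccna2 (2.64 ± 0.65) and the proliferation antigen gene Mki67 (2.45 ± 0.60). Of 28 matrix genes 7 rose (18 adjusted over the list alone), with Col1a1, a chain of type I collagen, at 10.2 ± 6.09 against 1.51 ± 0.809 CPM and the collagen cross-linking enzyme gene Lox 7.56-fold higher. Of 17 genes of lipid-associated macrophages 5 rose and 1 fell (13 and 1 adjusted over the list alone), including galectin-3 (Lgals3, 4.61-fold) and the glucan receptor gene Clec7a (5.43-fold). Camera gave these 3 lists adjusted p = 3.01e-10, 3.01e-10 and 8.11e-08, and adjusted p = 0.279, 0.282 and 0.279 with an estimated correlation. Of 12 NRF2 target genes 3 rose (5 adjusted over the list alone; camera adjusted p = 0.000179), led by the sulfiredoxin gene Srxn1 (2.79-fold). This list had adjusted p = 0.102 with an estimated correlation. Folds moved by over 1.5 times with 1 library left out were, as log2 values, 1.94, 4.06, 3.24, 0.68, 4.6, 1.4, 1.78 and 4.39 for Ccna2, Ccnb1, Cdc20, Fgf21, Gpnmb, Lgals3, Mki67 and Mmp12 without FFVHC replicate 2, 5.93, 4.06, 5.78 and 6.71 for Ccnb1, Cidec, Gsta1 and Mmp12 without LF replicate 3, and 6.72 for Gpnmb without LF replicate 4. The number of cell cycle genes called became 2, 2, 5 and 0 without LF replicates 1, 2, 3 and 4 and 1 without FFVHC replicate 2, and that of matrix genes 0 without any 1 of LF replicates 1, 2 or 4 and 11, 0 and 2 without FFVHC replicates 1, 2 and 4. The macrophage list had 0, 1 and 0 without LF replicates 1, 2 and 4 and 1 without FFVHC replicate 2, and the NRF2 list 0, 1 and 0 without LF replicates 1, 2 and 4 and 0 without FFVHC replicate 2.

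In all, edgeR called 344 genes, 260 higher and 84 lower in FFVHC than in LF at an adjusted p under 0.05. The count was 25, 33 and 10 without LF replicates 1, 2 and 4 and 48 and 178 without FFVHC replicates 2 and 4, and 0 of the 17 genes named here kept the call whichever library was left out. With the compared groups alone in the fit 210 genes passed and 8 of those named, and without a filter on low counts 150 and 12. For HF and FFHC at 8 weeks edgeR called 0 genes, with 990 and 1168 genes at an unadjusted p under 0.05, and DESeq2 called 8 and 5. With 1 library left out edgeR called 2 without LF replicate 3 and 1 without HF replicate 2 for HF, and 2 and 1 without LF replicates 1 and 3 for FFHC. In HF the acute-phase gene Saa1 had a log2 fold change of -4.57 ± 1.38 (adjusted p = 0.593), and in FFHC Cidec had 2.55 ± 0.84 (adjusted p = 0.514).

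The same diets were compared with LF in GF mice after 8 weeks (n = 3 per group). In FFVHC livers Sqle, which encodes the squalene epoxidase of cholesterol synthesis (chromosome 15, 59315077 to 59331192, GRCm38), stood at 2.60 ± 0.626 CPM (SD) against 46.6 ± 6.91 CPM in LF. Its log2 fold change was -4.16 ± 0.84 (SE; adjusted p = 0.0125). It was the 1 gene of the 24 of cholesterol synthesis that fell (12 adjusted over the list alone), and the list median was -0.93. Camera gave the list adjusted p = 6.16e-19, and adjusted p = 0.178 with an estimated correlation. Among the rises Adam11 had a log2 fold change of 2.36 ± 0.46. Of the 3 adipose genes tested, which include the adipsin gene Cfd (18.9 ± 22 against 0.0982 ± 0.0611 CPM), 0 passed over all genes and 2 rose when adjusted over the list alone. This list had camera adjusted p = 0.00202, and its adjusted p = 0.0344 with an estimated correlation stayed under 0.05. In FFHC livers 0 genes were called, and the cholesterol synthesis list had a median of -0.74 (camera adjusted p = 9.13e-12) and adjusted p = 0.348 with an estimated correlation. In HF livers the cathepsin E gene Ctse rose (21.9 ± 37.4 against 0.0986 ± 0.0208 CPM), carried by 1 library, replicate 1 at 65.1 CPM, without which its log2 fold change was 1.42 (adjusted p = 1 by edgeR). In all, edgeR called 9 genes higher and 1 lower in FFVHC, 1 higher in HF, and 0 in FFHC, where 643 genes had an unadjusted p under 0.05 and DESeq2 called 3. For FFVHC the count was 6 and 0 without LF replicates 2 and 3 and 0 without FFVHC replicate 3, and 0 of 2 genes named (Sqle and Adam11) kept the call whichever library was left out. For HF it was 0, 0 and 3 without LF replicates 1, 2 and 3 and 0 and 2 without HF replicates 1 and 2, and for FFHC 1 without FFHC replicate 1. The number of cholesterol synthesis genes called in FFVHC was 0 without LF replicate 3 and 0 without any 1 of FFVHC replicates 1, 2 or 3.

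Whether SPF and GF mice differed in their response to a diet was tested as the interaction of diet and microbiota. At 8 weeks edgeR called 0 genes for HF, 1 for FFHC and 0 for FFVHC, with 534, 794 and 1449 genes at an unadjusted p under 0.05, and DESeq2 called 2, 0 and 24. The gene called for FFHC was the gene model Gm37397 (3.28 ± 0.61, adjusted p = 0.0242), at 0.498 ± 0.0925 against 0.254 ± 0.0834 CPM in SPF and 0.0689 ± 0.0638 against 0.370 ± 0.0769 CPM in GF livers, chosen after its values were seen. With 1 library left out the count was 1 without any 1 of GF HF replicates 1, 2 or 3 for HF, and 9 without any 1 of GF FFVHC replicates 1 or 2 for FFVHC. For FFHC it was 0 without any 1 of SPF LF replicates 3 or 4, 0 without SPF FFHC replicate 1, 0 without any 1 of GF LF replicates 1 or 3, and 0 without any 1 of GF FFHC replicates 1 or 2. Gpnmb and Mmp12, which rose in SPF FFVHC livers, had interaction terms of 6.12 ± 4.08 (adjusted p = 0.65) and 5.33 ± 2.88 (adjusted p = 0.58), so a difference between SPF and GF mice in these responses was not detectable. Of the 16 cell cycle genes 5 had a larger response in SPF than in GF FFVHC mice when adjusted over the list alone and 0 over all genes (camera adjusted p = 2.89e-06), and adjusted p = 0.475 with an estimated correlation. Across the 15840 genes tested, the SPF and GF fold changes correlated with Pearson r = 0.11 ± 0.11 (jackknife SE over libraries) for HF, 0.11 ± 0.08 for FFHC and 0.07 ± 0.08 for FFVHC (Spearman rho = 0.08, 0.08 and 0.11). Genes are not independent replicates, and no p was computed for these correlations.

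After 24 weeks the SPF HF livers (n = 6) stood furthest from LF (n = 6). The antimicrobial lipocalin gene Lcn2 (chromosome 2, 32384633 to 32388252, GRCm38) rose from 32.2 ± 30.8 to 2806 ± 6233.7 CPM (SD), and 1 HF library, replicate 4, held 15522.9 CPM. Its log2 fold change was 6.44 ± 1.21 (SE; adjusted p = 9.14e-05), and 3.02 (adjusted p = 0.00962) without that library. The lipopolysaccharide co-receptor gene Cd14 rose 56.4-fold. Chil3, made by activated macrophages, rose 41.5-fold. Steep falls were seen in major urinary protein genes, whose reads paralogs may share: Mup15, Mup16, Mup17, Mup18 and Mup12 had log2 fold changes of -5.37, -3.91, -4.96, -3.86 and -3.83. Of 24 cholesterol synthesis genes 22 fell (23 adjusted over the list alone), with Tm7sf2, Pmvk, Nsdhl and Cyp51 at -2.06, -1.72, -2.05 and -1.99. Of 13 bile acid synthesis genes 5 fell and 1 rose (6 and 1 adjusted over the list alone), among the falls Akr1d1 (-1.50), Slc27a5 (-0.81), Cyp27a1 (-0.82) and the sterol 12-alpha-hydroxylase gene Cyp8b1 (-1.75). Slc10a1, the bile acid uptake transporter, had -2.11 ± 0.26. Of 11 hepatocyte genes 8 fell (9 adjusted over the list alone), such as the albumin gene Alb (-0.93) and Ttr (-0.54). These 3 lists had camera adjusted p = 1.08e-17, 0.000394 and 1.77e-05, and adjusted p = 0.202, 0.202 and 0.202 with an estimated correlation. With replicate 4 left out Cd14 had a log2 fold change of 1.36. Chil3 had 2.94 without HF replicate 3 and 6.08 without LF replicate 1, and Mup17, Mup18 and Lcn2 had -4.30, -3.23 and 7.10 without LF replicate 3.

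In the same SPF HF livers, genes of matrix, macrophages, neutrophils and the acute phase rose, the last 2 groups largely through 1 library each. Of 28 matrix genes 23 rose (25 adjusted over the list alone), among them Lum (3.88-fold), the basement membrane collagen gene Col4a1 (3.63-fold), the cross-linking enzyme gene Loxl2 (3.07-fold) and the microfibril gene Fbn1 (2.65-fold). Col1a1 (chromosome 11, 94936224 to 94953042, GRCm38) stood at 21.9 ± 7.78 against 4.94 ± 2.94 CPM (adjusted p = 0.00176). Of 17 genes of lipid-associated macrophages 15 rose and 1 fell (the same numbers adjusted over the list alone), with Lgals3 (7.76-fold), Lpl (5.79-fold) and the lysosomal tetraspanin gene Cd63 (8.68-fold). In the list of 12 Kupffer cell genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.58), and the haemoglobin-haptoglobin scavenger receptor gene Cd163 (-3.13 ± 0.59) and Timd4 (-2.08 ± 0.50) were the falls. All 10 neutrophil genes rose, also when adjusted over the list alone, among them Ngp (310.3-fold), the lactoferrin gene Ltf (253.1-fold), the cathelicidin gene Camp (175.3-fold) and the elastase gene Elane (17.2-fold). These folds rested on HF replicate 3, whose neutrophil score (mean log2 CPM) was 5.78 against 1.20 in the next HF library. Without it 1 of the 10 genes passed, and Ngp, Ltf, Camp and Elane had log2 fold changes of 3.66, 1.91, 1.04 and 0.17. Of 20 acute-phase genes 19 rose (the same number adjusted over the list alone), Il1rn 18.7-fold and Orm2 11.9-fold, and of 19 chemokine and inflammation genes 15 rose (also 15 adjusted over the list alone), with Icam1 6.11-fold and Cxcl2 22.7-fold higher. Without HF replicate 4, 5 of the 20 acute-phase genes passed, and Il1rn, Orm2, Icam1, Cxcl2, Cd63 and Col4a1 had log2 fold changes of 1.55, 1.88, 0.94, 1.39, 2.49 and 1.05. These 5 lists, Kupffer cells aside, had camera adjusted p = 3.22e-14, 1.67e-08, 0.00703, 0.000394 and 9.4e-07, and adjusted p = 0.202, 0.202, 0.447, 0.454 and 0.202 with an estimated correlation. In 1 of the 6 HF libraries, replicate 4, Saa1 reached 24283.5 CPM and Dbp 2.30 CPM, and 2 others, replicates 5 and 6, were among the 8 libraries high in Scand1. edgeR called 4588 genes for HF, 2887 higher and 1701 lower. With 1 library left out the count lay between 3836 and 4624, and 47 of 50 genes named for HF kept the call whichever library was left out (Camp, Elane and Ltf lost it without HF replicate 3). DESeq2 gave no adjusted p for Camp, Cd14 and Ltf, and with the compared groups alone in the fit 2968 genes passed and 49 of those named.

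**Figure D2:**
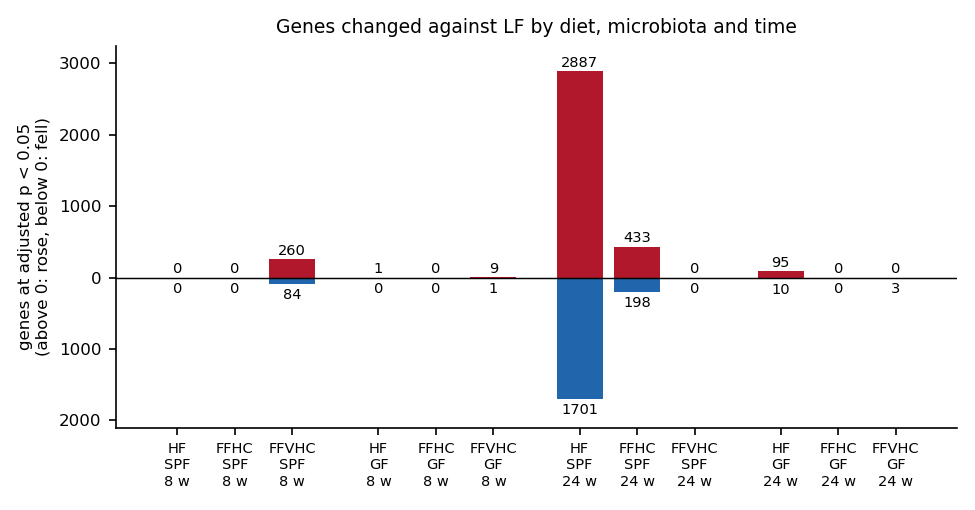
Genes at an adjusted p under 0.05 (edgeR) in each diet against LF, by housing and time, with genes that rose drawn above 0 and genes that fell below it. SPF HF at 24 weeks has the most, 2887 that rose and 1701 that fell.

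In SPF FFHC livers of 24 weeks (n = 6), some cholesterol synthesis genes fell and some genes of matrix, lipid-associated macrophages and cell division rose against LF. Sqle stood at 12.4 ± 7.09 against 64.6 ± 34.2 CPM (SD), a log2 fold change of -2.38 ± 0.53 (SE; adjusted p = 0.0103). In all 12 of the 24 genes of the list fell (18 adjusted over the list alone), Tm7sf2, Pmvk and Ebp with log2 fold changes of -1.44, -1.09 and -0.63. Gpnmb rose 6.89-fold to 19.7 ± 4.96 CPM, Trem2, a lipid receptor of such macrophages, 4.32-fold and Lgals3 4.06-fold, in a list of which 5 of 17 rose and 1, the fatty acid binding protein gene Fabp5 (-2.49), fell (13 and 1 adjusted over the list alone). Of 28 matrix genes 10 rose (22 adjusted over the list alone), such as Col6a1 (2.03-fold), Loxl2 (2.46-fold) and Lum (2.57-fold). Of 16 cell cycle genes 4 rose (12 adjusted over the list alone), including the replication helicase genes Mcm2 (2.65-fold) and Mcm5 (3.26-fold). Sdcbp2 rose 14.9-fold and Cyp21a1, which encodes steroid 21-hydroxylase, 9.97-fold, while Cyp2c40 (paralogs may share its reads) and Acpp had log2 fold changes of -3.46 and -2.32. The lists of cholesterol synthesis, lipid-associated macrophages, matrix and cell cycle had camera adjusted p = 2.15e-16, 2.28e-08, 5.13e-15 and 5.05e-08, and adjusted p = 0.208, 0.208, 0.208 and 0.315 with an estimated correlation. In all, edgeR called 631 genes, 433 higher and 198 lower. That count was 105, 371, 189, 121 and 988 without LF replicates 2, 3, 4, 5 and 6 and 186, 201 and 187 without FFHC replicates 1, 5 and 6, and 12 of the 17 genes named here kept the call whichever library was left out. The compared groups alone gave 2355 genes, no filter on low counts 314, and DESeq2 950 (without Gpnmb, adjusted p = 0.0554). The cholesterol synthesis genes called became 7 without any 1 of LF replicates 2 or 5 and 7 without any 1 of FFHC replicates 1 or 6, and the macrophage genes 2, 2, 2 and 11 without LF replicates 2, 4, 5 and 6 and 3 without any 1 of FFHC replicates 1 or 6. For matrix genes the number was 2, 5, 3, 2 and 18 without LF replicates 2, 3, 4, 5 and 6 and 5, 4 and 4 without FFHC replicates 1, 5 and 6, and for cell cycle genes 0, 0, 1 and 0 without LF replicates 2, 3, 4 and 5 and 0, 1, 1, 0 and 0 without FFHC replicates 1, 2, 4, 5 and 6.

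In SPF FFVHC livers of 24 weeks (n = 6) matrix and stellate cell genes lay above LF as lists under the preset correlation, though no single gene passed over all genes tested. Loxl2 had a log2 fold change of 1.20 ± 0.28 (SE; adjusted p = 0.0571), Col6a1 0.92 ± 0.23 and Col1a1 1.63 ± 0.52, and 24 of the 28 matrix genes passed when adjusted over the list alone. Of 12 stellate cell genes 8 passed when adjusted over the list alone, among them Rgs5 (1.09 ± 0.24) and the decorin gene Dcn (0.57 ± 0.17). Both lists had camera adjusted p = 7.57e-17 and 1.63e-05, and adjusted p = 0.154 and 0.154 with an estimated correlation. edgeR called 0 genes, with 2448 at an unadjusted p under 0.05, and DESeq2 called 175. With 1 library left out edgeR called 65 and 127 without LF replicates 1 and 6 and 206, 28 and 469 without FFVHC replicates 3, 5 and 6.

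The SPF diets were also compared with each other, FFHC with HF and FFVHC with FFHC. At 24 weeks FFHC livers held less of the acute-phase and neutrophil transcripts than HF livers (n = 6 each). Of 20 acute-phase genes 17 were lower (18 adjusted over the list alone), with Cd14, Apcs, Il1rn and Orm1 at log2 fold changes of -5.20, -3.39, -3.37 and -2.32. Of 10 neutrophil genes 6 were lower (9 adjusted over the list alone), among them Ngp (-7.63 ± 1.28) and Ltf (-7.86 ± 1.37), and the lipopolysaccharide-binding protein gene Lbp had -1.91 ± 0.42 (adjusted p = 0.0097). Cd163 stood 4.49-fold higher in FFHC and Susd4 4.14-fold. Both groups rested on 1 HF library each. Without HF replicate 4, 0 acute-phase genes passed, and Cd14, Apcs, Il1rn, Orm1 and Lbp had log2 fold changes of -0.75, -0.16, -0.71, -0.22 and -0.45. Without HF replicate 3, 0 neutrophil genes passed, and Ngp and Ltf had -2.99 and -1.77. Acute-phase genes numbered 10 without any 1 of FFHC replicates 3, 4 or 5. The 2 lists had camera adjusted p = 2.75e-08 and 0.00014, and for both adjusted p = 0.278 with an estimated correlation. For this pair edgeR called 187 genes, 23 higher and 164 lower in FFHC. This count was 124, 88, 69, 75 and 96 without FFHC replicates 1, 2, 3, 4 and 5 and 375, 393, 7 and 327 without HF replicates 1, 2, 4 and 5, and HF replicate 4 was the library with the highest Saa1 level. With the compared groups alone in the fit edgeR called 0 genes, and 0 of the 9 genes named kept the call whichever library was left out. Between FFVHC and FFHC at 24 weeks edgeR called 0 genes (656 at an unadjusted p under 0.05, 5 by DESeq2, 3 and 1 without FFVHC replicates 4 and 5 by edgeR), and 16 of 24 cholesterol synthesis genes were higher in FFVHC when adjusted over the list alone, Sqle with 2.53 ± 0.53 (adjusted p = 0.193). That list had camera adjusted p = 1.55e-20, and adjusted p = 0.148 with an estimated correlation. At 8 weeks (n = 4 each) edgeR called 0 genes in both comparisons, with 561 and 869 at an unadjusted p under 0.05, and DESeq2 called 2 and 0.

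In GF mice of 24 weeks the diets were set against 5 LF libraries. HF livers (n = 3) held more of Hdc, the histidine decarboxylase gene, at 28 ± 31.9 against 5.90 ± 2.01 CPM (SD), a log2 fold change of 2.25 ± 0.43 (SE; adjusted p = 0.00418). Phf11c rose 5.13-fold, the histone methyltransferase gene Setdb2 4.34-fold and Havcr2, which encodes the checkpoint receptor TIM-3, 3.59-fold. Among the falls were Map3k10 and Sap30l, with log2 fold changes of -0.68 and -0.62. Of 7 MHC class II genes 6 rose when adjusted over the list alone and 0 over all genes, with Cd74 at 1.37 ± 0.42 (camera adjusted p = 0.000367), and adjusted p = 0.64 with an estimated correlation. In FFVHC livers (n = 4) the 24 cholesterol synthesis genes had a median log2 fold change of -0.49 (camera adjusted p = 5.52e-18) and adjusted p = 0.212 with an estimated correlation, and 1 of them, Tm7sf2 (-1.03 ± 0.25), passed when adjusted over the list alone. The carboxypeptidase E gene Cpe (-4.32 ± 0.86), the proteoglycan gene Spock2 (-4.34 ± 0.84) and the integrin gene Itgae (-2.22 ± 0.44) fell, all 3 with a mean of 2.10 CPM or less on LF and chosen after their values were seen. In all, edgeR called 95 genes higher and 10 lower in HF, 3 lower in FFVHC, and 0 in FFHC (n = 3), where 539 genes had an unadjusted p under 0.05 and DESeq2 called 2. The count for HF was 54, 36 and 27 without LF replicates 2, 3 and 4 and 408, 0 and 757 without HF replicates 1, 2 and 3, 0 of the 6 genes named kept the call without HF replicate 2, and the compared groups alone gave 0. Without HF replicate 2 Hdc, Setdb2 and Havcr2 had log2 fold changes of 0.71, 1.15 and 1.01, and for FFVHC Cpe had -3.67 without LF replicate 2. For FFVHC it was 1, 1 and 7 without LF replicates 1, 2 and 3 and 0 without any 1 of FFVHC replicates 1, 3 or 4 (0 of the 3 genes named kept the call whichever library was left out), and for FFHC 1 without LF replicate 5. With the set of 8 libraries as a covariate, chosen after seeing the data, edgeR called 24 genes for HF and 0 for FFVHC.

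At 24 weeks edgeR called 191 genes for the interaction of HF and housing, 58 with a higher and 133 with a lower change in SPF mice. Of 24 cholesterol synthesis genes 5 had the lower change in SPF mice (14 adjusted over the list alone), Tm7sf2 with -1.82 ± 0.34 (adjusted p = 0.00489) and Nsdhl -2.23 ± 0.48. Of 13 bile acid synthesis genes 2 did so (5 adjusted over the list alone), Cyp27a1 (-1.24 ± 0.26) and Cyp7b1 (-2.65 ± 0.63). Of 14 male-biased genes 4 did so (10 adjusted over the list alone), Mup11 with -8.82. Among Kupffer cell genes Cd163 (-3.93 ± 0.86) and Timd4 (-2.77 ± 0.75) were the 2 of 12 called (3 adjusted over the list alone). The adipocyte fatty acid binding protein gene Fabp4 (3.52 ± 0.85) and Slc25a24 (2.43 ± 0.66) had the higher change in SPF mice. So had Scand1 (5.50), H2aj (2.66) and Tmem238 (2.58), which set apart the 8 libraries high in Scand1 (2 of 6 SPF HF and 3 of 5 GF LF among them). Camera gave cholesterol synthesis, bile acid synthesis, male-biased and Kupffer cell genes adjusted p = 3.15e-10, 4.98e-06, 6.31e-08 and 0.0482, and adjusted p = 0.274, 0.0911, 0.253 and 0.565 with an estimated correlation. With the set of 8 libraries as a covariate, chosen after seeing the data, edgeR called 4 genes for HF, all lower in SPF mice, and 1 of the 12 genes named kept the call, and with the compared groups alone 17 and 2. The count for HF was 108 without SPF LF replicate 4, 335 without SPF HF replicate 4, 43 without GF LF replicate 4, and 708 and 20 without GF HF replicates 1 and 2. Interaction terms moved by over 1.5-fold became -3.03, -8.11 and -1.52 for Cd163, Mup11 and Timd4 without GF HF replicate 2, 1.5 for Fabp4 without SPF HF replicate 4, -9.57 for Mup11 without GF LF replicate 5, and 4.87 for Scand1 without SPF HF replicate 6. Cholesterol synthesis genes called became 3 without SPF LF replicate 2, 2 without GF LF replicate 4, and 3 without any 1 of GF HF replicates 1 or 3, bile acid synthesis genes 1 without GF LF replicate 4 and 0 without GF HF replicate 2, and male-biased genes 2 without GF LF replicate 4 and 10 and 1 without GF HF replicates 1 and 2. Of Kupffer cell genes 0 were called without GF HF replicate 2, and 1 without any 1 of 13 other libraries. For FFVHC edgeR called 7 genes with a higher change in SPF mice, among them the mesothelin gene Msln (6.60 ± 1.37) and Igfbp5 (3.94 ± 0.74). For FFHC it called 0, with 1581 at an unadjusted p under 0.05 and 3 by DESeq2. For FFVHC the count was 3, 3, 3, 3, 4 and 25 without SPF LF replicates 1, 2, 3, 4, 5 and 6, 3, 3, 3 and 11 without SPF FFVHC replicates 1, 2, 4 and 5, 1, 22 and 3 without GF LF replicates 2, 3 and 4, and 4, 1 and 1 without GF FFVHC replicates 1, 3 and 4. Its terms became 7.32, 5.96 and 7.95 for Msln without SPF LF replicate 6, GF LF replicate 2 and GF FFVHC replicate 1. The count was 1 with the set of 8 libraries as a covariate and 0 with the compared groups alone. Across the 15840 genes the SPF and GF fold changes correlated with Pearson r = 0.35 ± 0.23 (jackknife SE) for HF, -0.03 ± 0.23 for FFHC and 0.10 ± 0.33 for FFVHC (Spearman rho = 0.33, -0.05 and 0.10), and no p was computed. For HF r was 0.13 and 0.18 without GF HF replicates 1 and 2.

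**Figure D3:**
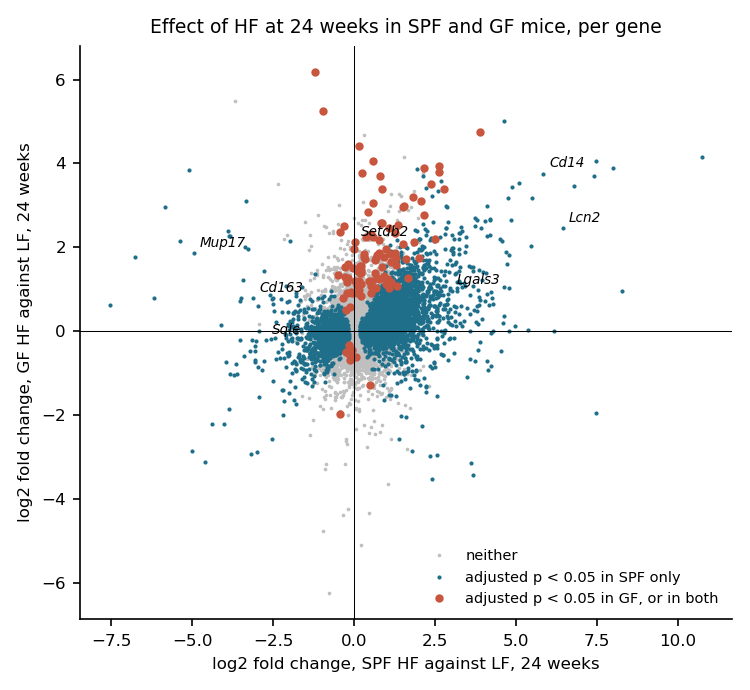
Log2 fold change of HF against LF at 24 weeks in SPF (horizontal axis) and GF mice (vertical axis), 1 point per gene tested, coloured by the test in either housing, which does not test the difference between them. Across the 15840 genes Pearson r is 0.35, and Lcn2, Cd14 and Lgals3 lie at the right.

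SPF and GF livers were next compared within each diet. After 8 weeks on LF (4 SPF, 3 GF) Igfbp1, which encodes an insulin-repressed growth factor binding protein (chromosome 11, 7197782 to 7202546, GRCm38), stood at 9.83 ± 4.66 CPM (SD) in SPF against 904.5 ± 472.6 CPM in GF livers. Its log2 fold change was -6.52 ± 1.11 (SE; adjusted p = 0.000542). The immediate early gene Egr1, the p21 gene Cdkn1a, Btg2 and the clock gene Arntl were lower in SPF livers too, at -5.13, -5.12, -3.64 and -3.52. Csad, a taurine synthesis enzyme gene, stood 13.7-fold higher in SPF livers, and Raet1e 23.4-fold and Raet1d 23.1-fold (ligands of the receptor NKG2D, with reads that paralogs may share). Of 12 gluconeogenesis and insulin response genes 2 were lower in SPF LF livers (5 adjusted over the list alone), Igfbp1 and Irs2 (-2.60), and of 20 lipogenesis genes 3 (9 adjusted over the list alone), among them Acacb (-1.99) and the stearoyl-CoA desaturase gene Scd1 (-1.50). These 2 lists had camera adjusted p = 4.23e-05 and 4.92e-05, and adjusted p = 0.0974 and 0.896 with an estimated correlation. On HF Cdkn1a (-3.75) was lower in SPF livers, and Raet1e (4.47) and Csad (2.16) higher. On FFHC the metallothionein genes Mt1 (-5.74) and Mt2 (-6.59) were lower, Mmp12 (5.57) was higher, and 4 of 20 acute-phase genes were lower (10 adjusted over the list alone), Steap4 among them (-2.71). That list had camera adjusted p = 3.5e-05, and adjusted p = 0.84 with an estimated correlation. On FFVHC Gpnmb (7.37 ± 1.80, adjusted p = 0.00841), Mmp12 (6.84 ± 1.56) and Gsta1 (5.44 ± 1.23) were higher in SPF livers and Fgl1 (-2.26) lower. There 11 of 17 genes of lipid-associated macrophages were higher (14 adjusted over the list alone). So were 5 of 18 interferon response genes (12 higher and 1 lower adjusted over the list alone), such as Ifit3 (1.11), and 6 of 12 NRF2 targets (7 higher and 1 lower adjusted over the list alone), such as the quinone reductase gene Nqo1 (1.56). These 3 lists had camera adjusted p = 4.13e-08, 2.75e-05 and 0.00193, and adjusted p = 0.431, 0.461 and 0.341 with an estimated correlation. In all, edgeR called 93 genes higher and 224 lower in SPF than in GF livers on LF, 124 and 254 on HF, 624 and 868 on FFHC, and 744 and 745 on FFVHC. With 1 library left out these totals were 152, 204 and 85 without SPF LF replicates 2, 3 and 4 and 63, 110 and 197 without GF LF replicates 1, 2 and 3. For HF they were 67, 231, 146 and 163 without SPF HF replicates 1, 2, 3 and 4 and 13 and 180 without GF HF replicates 2 and 3, for FFHC 862 without SPF FFHC replicate 1 and 767 and 640 without GF FFHC replicates 1 and 3. On FFVHC they were 634 without SPF FFVHC replicate 2 and 358, 841 and 617 without GF FFVHC replicates 1, 2 and 3. With the log2 ratio of Dbp to Arntl as a covariate, chosen after seeing the data, 184 genes passed on LF, where phase and housing cannot be told apart for genes such as Igfbp1, Egr1, Btg2 and Arntl, and 8 of 11, 2 of 3, 0 of 4 and 5 of 6 genes named for LF, HF, FFHC and FFVHC kept the call. Folds moved by over 1.5 times became, on the log2 scale, 5.56 for Raet1e without GF LF replicate 3 on LF. On FFHC they became 3.94 and -7.36 for Mmp12 and Mt2 without SPF FFHC replicate 4 and -4.93, -5.73 and -2.06 for Mt1, Mt2 and Steap4 without GF FFHC replicate 1. On FFVHC they became 6.16 and 5.64 for Gpnmb and Mmp12 without SPF FFVHC replicate 2, 8.89 for Gpnmb without GF FFVHC replicate 2, and 7.97 for Mmp12 without GF FFVHC replicate 3. On LF the lipogenesis genes called were 1, 1 and 0 without SPF LF replicates 2, 3 and 4 and 1 and 0 without GF LF replicates 1 and 3, and those of gluconeogenesis 1 without GF LF replicate 1. Acute-phase genes on FFHC were 2 without any 1 of SPF FFHC replicates 1, 2 or 4 and 0 and 2 without GF FFHC replicates 1 and 3. On FFVHC macrophage genes were 4 without SPF FFVHC replicate 2 and 1 and 7 without GF FFVHC replicates 1 and 2, interferon response genes 0 without SPF FFVHC replicate 2 and 0, 2 and 3 without GF FFVHC replicates 1, 2 and 3, and NRF2 targets 2 without GF FFVHC replicate 2.

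**Figure D4:**
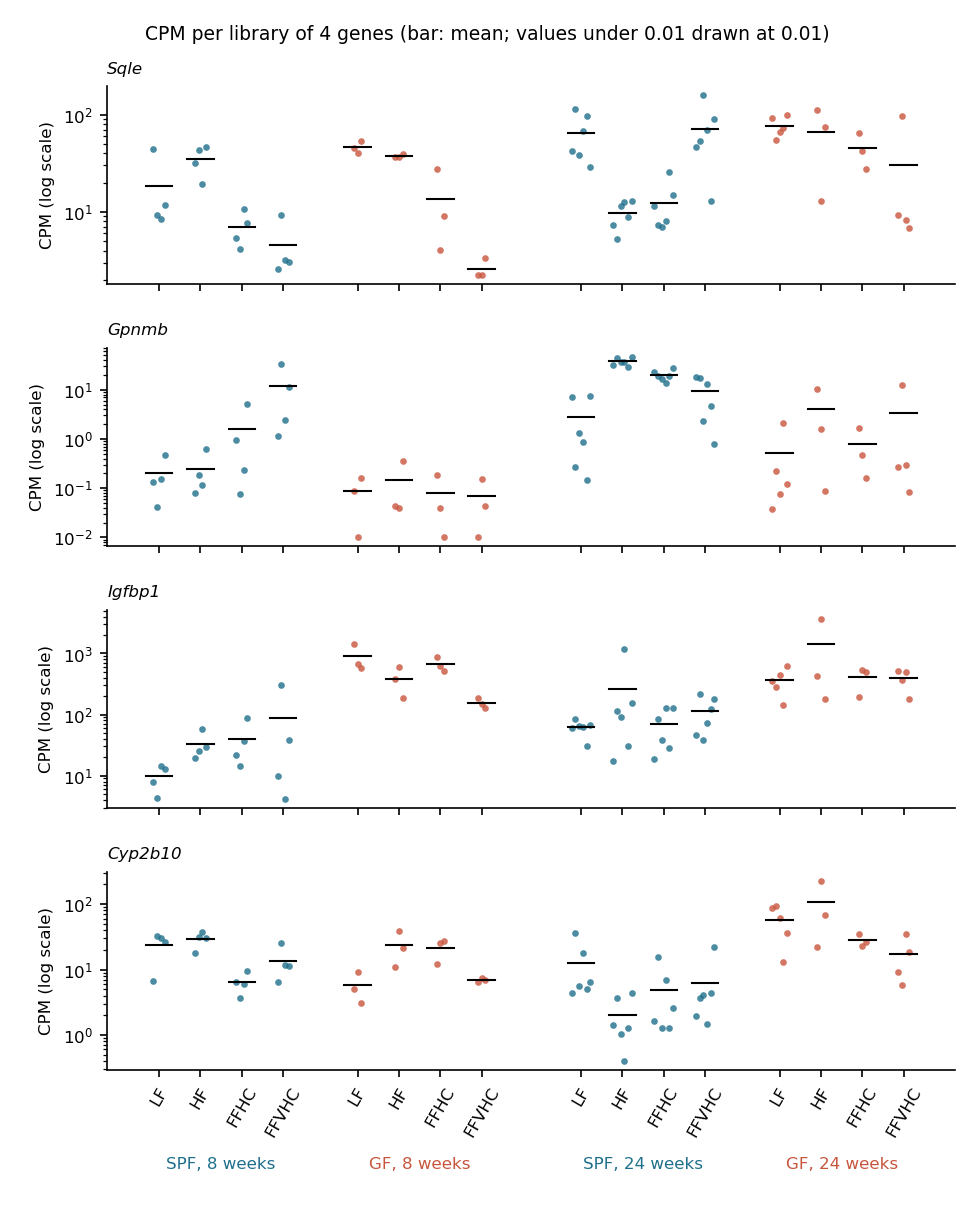
CPM (log scale) of Sqle, Gpnmb, Igfbp1 and Cyp2b10 in each of the 67 libraries, by group, with bars at the group means. Igfbp1 averages 9.83 ± 4.66 CPM (SD) in SPF LF and 904.5 ± 472.6 CPM in GF LF livers at 8 weeks.

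After 24 weeks on LF (6 SPF, 5 GF) Csad (3.11 ± 0.41, adjusted p = 6.18e-06), the hepcidin gene Hamp (2.98 ± 0.70) and the E-cadherin gene Cdh1 (2.87 ± 0.61) were higher in SPF livers and Nnt lower (-1.55 ± 0.23). Of 23 fatty acid oxidation genes 2 were lower (8 adjusted over the list alone), Ehhadh (-0.82 ± 0.18) and Cyp4a31 (-1.15 ± 0.29, paralogs may share its reads), with camera adjusted p = 8.96e-08 and adjusted p = 0.643 with an estimated correlation. On HF (6 SPF, 3 GF) Cyp2b10, a target of the xenobiotic receptor CAR (chromosome 7, 25897620 to 25926624, GRCm38), stood at 2.02 ± 1.57 CPM (SD) in SPF against 106 ± 107.7 CPM in GF livers. Its log2 fold change was -5.69 ± 0.77 (SE; adjusted p = 3.98e-07). GF HF replicate 2 held 227.6 CPM, and without it the log2 fold change was -4.46 (adjusted p = 0.000102). There Cd163 (-4.75) and Susd4 (-5.00) were also lower in SPF livers, and Chil3 (6.46), the monocyte chemokine gene Ccl2 (4.72) and Mmp7 (4.43) higher. Of 13 bile acid synthesis genes 8 were lower in SPF HF livers (10 adjusted over the list alone), such as Cyp27a1 (-1.42) and Cyp7b1 (-2.82). Of 12 gluconeogenesis and insulin response genes 9 were lower (also 9 adjusted over the list alone), such as Pck1 (-1.85), and of 11 hepatocyte genes 8 were (10 adjusted over the list alone), such as Hnf4a (-1.46). Camera gave these 3 lists adjusted p = 5.06e-07, 1.32e-05 and 2.16e-07, and each kept the call with an estimated correlation (adjusted p = 0.0449). They are 3 of only 4 calls so kept in 1155 list tests. Camera was not rerun without SPF HF replicate 4, lowest of its group in bile acid synthesis and hepatocyte scores. On FFHC (6 SPF, 3 GF) Gpnmb (4.58 ± 1.29) and Cyp21a1 (5.17 ± 0.99) were higher in SPF livers, and Arntl (-3.14 ± 0.71) and the hepcidin paralog Hamp2 (-3.23 ± 0.76) lower. All 7 MHC class II genes were higher there, also when adjusted over the list alone. Higher as well were 12 of 18 interferon response genes (14 adjusted over the list alone), such as Oasl2 (1.58) and Ifit2 (1.73), and 12 of 17 genes of lipid-associated macrophages (also 12 adjusted over the list alone), such as the osteopontin gene Spp1 (2.93) and Cd68 (1.49). These 3 lists had camera adjusted p = 2.12e-06, 3.83e-08 and 7.73e-08, and for each adjusted p = 0.233 with an estimated correlation. On FFVHC (6 SPF, 4 GF) the sterol transporter genes Abcg5 (-2.04 ± 0.29, adjusted p = 4.69e-05; chromosome 17, 84658234 to 84683011, GRCm38) and Abcg8 (-2.08 ± 0.31) were lower in SPF livers. Igfbp5 (2.99 ± 0.58) and the chemokine gene Cxcl10 (2.62 ± 0.52) were higher. Of 9 cholangiocyte genes 7 were higher (8 adjusted over the list alone), such as Krt7 (2.42) and Epcam (2.16), and of 28 matrix genes 20 (22 higher and 1 lower adjusted over the list alone), such as Col1a2 (1.91). Both had camera adjusted p = 4.13e-06 and 5.17e-12, and adjusted p = 0.0765 and 0.132 with an estimated correlation. In all, edgeR called 54 genes higher and 75 lower in SPF livers on LF, 2582 and 2064 on HF, 1251 and 858 on FFHC, and 949 and 681 on FFVHC. Leaving out 1 library changed the totals to 33, 45, 72 and 79 without SPF LF replicates 3, 4, 5 and 6 and 18, 34, 314 and 77 without GF LF replicates 2, 3, 4 and 5. For HF and FFHC they became 2958 without GF HF replicate 2, and 907 and 1201 without GF FFHC replicates 2 and 3. For FFVHC they became 903, 1081 and 735 without SPF FFVHC replicates 1, 2 and 4 and 659, 2743, 386 and 667 without GF FFVHC replicates 1, 2, 3 and 4. With the compared groups alone in the fit 1011 genes passed on HF and 83 on FFVHC, and with the set of 8 libraries as a covariate 83 on LF, where 3 of the 6 genes named kept the call. Log2 fold changes moved by over 1.5-fold became 2.50 for Csad without SPF LF replicate 4 and 4.13 for Hamp without GF LF replicate 3 on LF. On HF they became 2.50 and 3.41 for Ccl2 and Mmp7 without SPF HF replicate 4, -3.86 for Cd163 without GF HF replicate 2, and 4.04 for Chil3 without SPF HF replicate 3. On FFHC and FFVHC they became 5.84 and 5.84 for Cyp21a1 and Gpnmb without GF FFHC replicate 1, and 2.68 for Col1a2 without GF FFVHC replicate 2. Without GF HF replicate 2 the bile acid synthesis and gluconeogenesis genes called on HF were 5 and 5. Fatty acid oxidation genes on LF were 1, 1, 0, 1 and 1 without SPF LF replicates 1, 2, 4, 5 and 6 and 1, 0, 1 and 4 without GF LF replicates 1, 2, 3 and 4. On FFHC MHC class II genes were 3 and 4 without GF FFHC replicates 2 and 3, interferon response genes 7 and 5 without GF FFHC replicates 1 and 2, and macrophage genes 5 and 6 without GF FFHC replicates 2 and 3. Cholangiocyte genes on FFVHC were 4 without SPF FFVHC replicate 4 and 4, 2 and 4 without GF FFVHC replicates 1, 3 and 4, and matrix genes 11 without SPF FFVHC replicate 4 and 5, 4 and 6 without GF FFVHC replicates 1, 3 and 4.

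**Figure D5:**
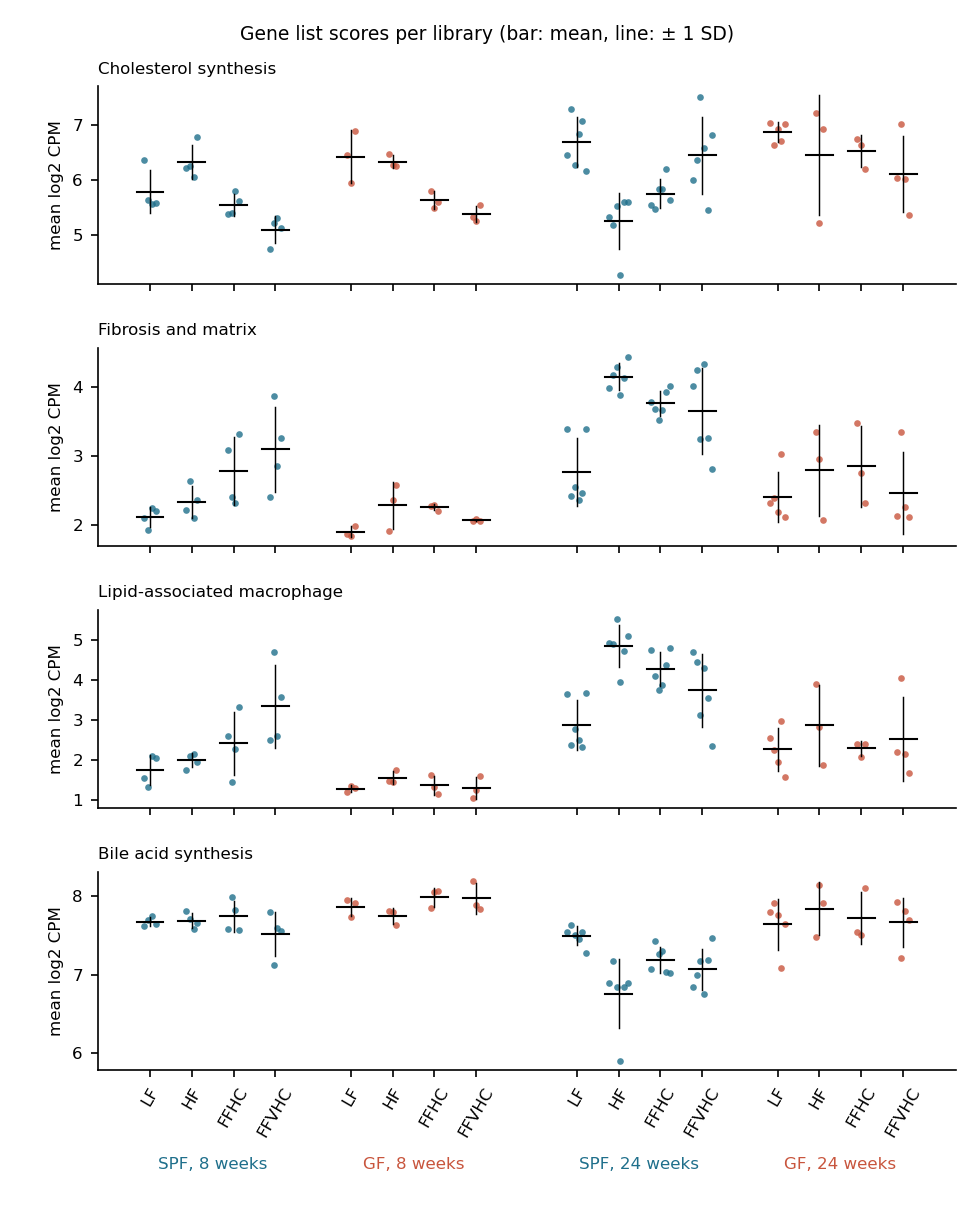
Mean log2 CPM over the genes of 4 lists in each library, by group, with bars at the group means and lines of 1 SD to either side. In SPF HF livers at 24 weeks the matrix score averages 4.16 ± 0.20 (SD) and that of lipid-associated macrophages 4.85 ± 0.52, against 2.77 ± 0.49 and 2.88 ± 0.63 in SPF LF, and cholesterol synthesis 5.25 ± 0.52 against 6.69 ± 0.46.

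The last question was what changed between 8 and 24 weeks, over the mean of the 4 diets. In SPF livers (16 against 24 libraries) Gpnmb (3.56 ± 0.58, SE; adjusted p = 2.38e-06) and the protease inhibitor gene Slpi (3.61 ± 0.44) rose. The steroid dehydrogenase gene Hsd3b5 (-4.62) fell. Of 28 matrix genes 26 rose, of 17 genes of lipid-associated macrophages 15 rose and of 16 cell cycle genes all 16 rose, the same numbers as adjusted over the list alone, with Trem2 at 1.96 and Mki67 at 1.47. Of 14 male-biased genes 12 fell and of 13 bile acid synthesis genes 9 fell, again the same numbers over the list alone. These 5 lists had camera adjusted p = 1.5e-12, 4.43e-09, 5.38e-07, 1.01e-06 and 2.19e-06, and adjusted p = 0.162, 0.162, 0.252, 0.225 and 0.162 with an estimated correlation. In GF livers (12 against 15 libraries) the lipid droplet gene Cidea (5.23 ± 0.91, adjusted p = 4.23e-05), Mmp12 (4.36 ± 0.81) and Raet1d (2.73 ± 0.28) rose, and the heat shock gene Hspa1a (-1.83) fell. There too genes of lipid-associated macrophages (12 of 17, 14 adjusted over the list alone) and matrix rose (17 of 28, while 2 fell, the same numbers over the list alone). Of 24 cholesterol synthesis genes 13 rose (16 adjusted over the list alone), such as Hmgcs1 (1.42) and Sqle (1.71), and of 15 lipid droplet genes 8 (10 adjusted over the list alone), such as Cidec (2.35). These 4 lists had camera adjusted p = 2.02e-06, 0.000859, 6.46e-05 and 0.000859, and for each adjusted p = 0.843 with an estimated correlation. In SPF livers 15 cholesterol synthesis genes rose and 2 fell (16 and 2 adjusted over the list alone), as 8 lipid droplet genes rose and 1 fell (10 and 1 over the list alone), with camera adjusted p = 0.0735 and 0.00874, and adjusted p = 0.741 and 0.406 with an estimated correlation. Whether these changes differed by housing was not tested. Age and harvest are confounded with time, as partly is Nnt in GF livers (low in 7 of 12 at 8 weeks only). Over the 4 diets edgeR called 4126 genes higher and 2932 lower at 24 weeks in SPF livers and 2010 and 1900 in GF livers. With 1 library left out they summed to 6551 to 7412 genes in SPF and 3172 to 4266 in GF livers, and all genes named kept the call. Log2 folds moved by over 1.5 times were those of GF livers. Cidea had 6.78, 5.95 and 5.96 without 8-week HF replicate 1, FFHC replicate 3 and FFVHC replicate 3. Mmp12 had 3.67 without 24-week FFVHC replicate 2. The difference of HF from LF in SPF mice changed with time in 624 genes, 318 upward and 306 downward. Lcn2 (10.11 ± 1.85, adjusted p = 0.00145) moved upward and Sqle (-3.65 ± 0.83) downward. Of 20 acute-phase genes 14 moved upward (16 adjusted over the list alone) and of 24 cholesterol synthesis genes 18 downward (23 adjusted over the list alone). Both had camera adjusted p = 1.22e-08 and 4.04e-26, and adjusted p = 0.277 and 0.101 with an estimated correlation. For FFHC and FFVHC edgeR called 0 genes whose difference from LF changed with time, with 534 and 947 at an unadjusted p under 0.05, and DESeq2 called 4 and 1. The count for HF was 384 and 222 without SPF LF 8-week replicates 2 and 4, 218 and 228 without SPF HF 8-week replicates 1 and 4, and 357 and 356 without SPF LF 24-week replicates 2 and 5. Terms moved by over 1.5-fold were -4.54 for Sqle and 8.91 for Lcn2 without SPF LF 8-week replicate 1. Lcn2 had 11.01, 10.76 and 6.68 without HF 8-week replicate 3, LF 24-week replicate 3 and HF 24-week replicate 4. Acute-phase genes called were 9 without any 1 of SPF HF 8-week replicates 1 or 4 and 4 without SPF HF 24-week replicate 4, and cholesterol synthesis genes 11 without SPF HF 8-week replicate 4. The count for FFVHC was 1 without SPF LF 8-week replicate 3.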

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

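The tests of GC content, of a single HF library and of other splits of the libraries were set before their results were seen. Those of depth, of diet, housing or time, of a strain variant, of housing alone, of the set of 8 libraries as a covariate and of the hepatocyte share were chosen after.

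In 8 libraries of 5 groups Scand1, H2aj, Mrps34 and Tmem238 stood apart, Scand1 with 11.1 to 20.5 CPM against 0.378 to 3.87 CPM in the other 59, and in all 146 genes were higher and 13 lower in the 8. Diet, housing or time as the source is argued against because all 5 groups with a library among the 8 also held other libraries. Depth is argued against. Of the 8, 1 was among the 5 libraries of 52262083 or more (at least 72.6% of low counts even, as if counted 2 times). The rest held 27055828 to 28507149 counts, as did other libraries. A candidate explanation is a bias of GC content between library batches, since the genes higher in the 8 had a median GC content of 57.2%, which is 8.0 percentage points above the 49.2% of all genes tested. No batch is given in the labels, the transcripts of those genes were also shorter (median 1665 against 3108 bases), and no biological explanation other than the groups was tested.

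The 40 SPF libraries held 37.2 to 74.1 CPM of Nnt and the 15 GF libraries of 24 weeks 114.6 to 197.9 CPM, while the 12 GF libraries of 8 weeks fell at 2 levels, 5 at 154.2 CPM or more and 7 at 76.0 CPM or less. Germ-free housing alone is argued against by 6 of those 12 libraries inside the range of the SPF libraries. Depth is argued against: 1 of the same 5 aside, the higher level held 24607892 to 29267798 counts, inside the range of the lower. A strain variant is a candidate explanation: some C57BL/6 substrains are known to carry a deletion in Nnt, the labels give no substrain, and the rank of the gap between the 2 levels, 4 among all genes tested, decides nothing because Nnt was picked for these levels. At 24 weeks the level follows the housing, so any effects of substrain and microbiota are confounded there.

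In SPF mice of 24 weeks edgeR called 4588 genes for HF, 631 for FFHC and 0 for FFVHC (2448 at an unadjusted p under 0.05 and 175 by DESeq2), and for HF matrix genes rose while cholesterol synthesis genes fell. The single HF library with an acute-phase profile, replicate 4, is argued against as the whole cause because 4019 genes passed without it, more than 1.5 times the FFHC count (946.5), although without it the direct comparison of FFHC with HF fell from 187 to 7 genes and the acute-phase genes called for HF from 19 to 5. With the compared groups alone in the fit the counts were 2968 for HF and 2355 for FFHC, less than 1.5 times apart, and FFHC reached 988 without LF replicate 6, so the size of the difference depends on the fit and on single libraries. With the set of 8 libraries as a covariate the counts were 4293 and 654. The lipid-associated macrophage median lay 2.16 (log2) above that of Kupffer cell genes. As some of these fell, this cannot decide on a lower hepatocyte share. A response to the diet is left as a hypothesis, found and tested on the same data.

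Single libraries stood apart in their group by a gap to the nearest other library that took up most of the group's range. Of 210 combinations of group and measure 26 did so, where chance gives about 1 in 20, or 10.5. SPF HF replicate 4 of 24 weeks did so in 9 measures: it had 19976 genes with a count against 22037 in the next library (ratio of gap to range 0.73), the highest acute-phase score, 12.1 (log2 CPM) against 8.48 (0.75), and the lowest scores for cholesterol synthesis (4.26, ratio 0.68), lipogenesis (5.66, 0.66), bile acid synthesis (5.90, 0.74), MHC class II (3.04, 0.73), cell cycle (-0.20, 0.72), cholangiocytes (1.5, 0.69) and hepatocytes (9.88, 0.65). Replicate 3 of the same group had a neutrophil score of 5.78 against 1.20 (0.70). SPF FFVHC replicate 2 of 8 weeks had the highest neutrophil (-0.14, ratio 0.93) and interferon response scores (4.11, 0.88) and the lowest hepatocyte score (11.04, 0.83) of its group. SPF LF replicate 1 of 8 weeks had the highest cholesterol synthesis (6.37, ratio 0.90) and lowest Kupffer cell scores (3.77, 0.84). SPF HF replicate 3 of 8 weeks had the lowest lipogenesis (7.66, ratio 0.88) and highest acute-phase scores (7.81, 0.92), and SPF FFHC replicate 2 of 8 weeks the lowest interferon response score (2.56, 0.84). GF FFVHC replicate 2 of 24 weeks had the highest matrix (3.35, ratio 0.88) and cell cycle scores (1.80, 0.86) of its group. GF LF replicate 4 of 24 weeks had the lowest hepatocyte score (11.2, ratio 0.72), and replicate 2 the highest share of mitochondrially encoded counts (6.44% against 5.17%, ratio 0.74). The 6 GF groups of 3 were not tested. Among them, GF FFVHC replicate 3 of 8 weeks held 55737.2 CPM of the gene model CT010467.1 (chosen after its values were seen), 5.57% of its counts, against at most 5159.1 CPM in any other library. GF HF replicate 2 of 24 weeks, without which 0 genes were called for HF in GF mice, had the lowest log2 ratio of Dbp to Arntl of all 67 libraries, -4.1. Total counts stood apart in 4 of the 5 libraries of 52262083 or more (ratios 0.95, 0.87, 0.98 and 0.88).

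Genes were called in 4 tests of a difference in diet response between groups. The interaction with housing called 1 gene for FFHC at 8 weeks, 191 genes for HF at 24 weeks, among them Tm7sf2 and Cd163, and 7 for FFVHC at 24 weeks, among them Msln. That with time in SPF mice called 624 genes for HF, among them Lcn2 and Sqle. Other splits of the same libraries were counted on fits of the compared groups alone, where the real counts were 0, 17, 0 and 454. As many genes were called in 100, 6, 100 and 4 of 100 splits, the real ones included. The highest of the other splits gave 2681, 820, 890 and 4301, all above the real ones. Labels were exchanged between SPF and GF libraries, or between 8 and 24 weeks, within a diet, so the splits carry the difference of housing or of time itself, in their counts or in the spread within a group. They are thus not draws without an interaction, and they decide nothing about chance.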

How the results depend on the processing

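3 alternatives were chosen after seeing the data: the halved counts of 5 libraries, the set of 8 libraries as a covariate and the clock covariate. No direction reversed under any alternative among the 211 named values. Counts of genes have no direction and were compared by size only. With DESeq2's size factors all 35 counts stayed within 1.5 times, as they did with halved counts. With DESeq2 in place of edgeR 9 of 35 counts of genes stayed within 1.5 times, and the other 26 were 8 for HF, 5 for FFHC and 710 for FFVHC against LF in SPF mice of 8 weeks, and 7 for HF, 3 for FFHC and 21 for FFVHC against LF in GF mice of 8 weeks. It gave 950 for FFHC and 175 for FFVHC against LF in SPF mice of 24 weeks, and 214 for HF, 2 for FFHC and 16 for FFVHC against LF in GF mice of 24 weeks. In the interaction with housing there were 2 for HF, 0 for FFHC and 24 for FFVHC at 8 weeks. At 24 weeks there were 416, 3 and 25 in that order. Between SPF and GF mice it gave 505 for LF and 570 for HF at 8 weeks, and 277 for LF at 24 weeks. Between SPF diets there were 2 for FFHC against HF at 8 weeks. At 24 weeks there were 354 for that pair and 5 for FFVHC against FFHC. It gave 1017 for HF, 4 for FFHC and 1 for FFVHC in the interaction with time. Without a filter on low counts, so with more genes tested, 14 counts moved, to 150 for FFVHC against LF in SPF mice of 8 weeks, and 314 for FFHC against LF in SPF mice of 24 weeks. It gave 69 for HF against LF in GF mice of 24 weeks, and 0 for FFHC and 2 for FFVHC in the interaction with housing at 8 weeks. There were 79 for HF in the interaction with housing at 24 weeks, and 176 for LF, 114 for HF, 826 for FFHC and 849 for FFVHC between SPF and GF mice at 8 weeks. It gave 42 for LF, 1380 for FFHC and 942 for FFVHC between SPF and GF mice at 24 weeks, and 303 for HF in the interaction with time. With only the compared groups in the fit, and so fewer libraries to measure the spread, 17 moved, to 1 for HF and 210 for FFVHC against LF in SPF mice of 8 weeks, and 0 for HF against LF in GF mice of 8 weeks. It gave 2968 for HF and 2355 for FFHC against LF in SPF mice of 24 weeks, and 0 for HF and 0 for FFVHC against LF in GF mice of 24 weeks. There were 0 for FFHC in the interaction with housing at 8 weeks, and 17 for HF, 6 for FFHC and 0 for FFVHC in the interaction with housing at 24 weeks. Between SPF and GF mice it gave 508 for LF and 173 for HF at 8 weeks. At 24 weeks it gave 1011 for HF and 83 for FFVHC. There were 0 for FFHC against HF between SPF diets at 24 weeks, and 1 for FFHC in the interaction with time. With the set of 8 libraries as a covariate 5 counts moved, to 24 for HF and 0 for FFVHC against LF in GF mice of 24 weeks, and 4 for HF and 1 for FFVHC in the interaction with housing at 24 weeks. It gave 83 for LF between SPF and GF mice at 24 weeks. The clock covariate, run for the 8 comparisons of SPF and GF mice, moved 1, LF at 8 weeks, to 184. With the correlation estimated from the data 4 of 411 list calls held. For the moved counts the cause was not tested, apart from the fewer or more genes and libraries named. With each library left out in turn the lowest and highest counts of genes were 0 to 2 for HF, 0 to 2 for FFHC and 10 to 453 for FFVHC against LF in SPF mice of 8 weeks, and 0 to 3 for HF, 0 to 1 for FFHC and 0 to 13 for FFVHC against LF in GF mice of 8 weeks. Against LF at 24 weeks ranges were 3836 to 4624, 105 to 988 and 0 to 469 for HF, FFHC and FFVHC in SPF mice. In GF mice they were 0 to 757, 0 to 1 and 0 to 7. In the interaction with housing they were 0 to 1 for HF and FFHC and 0 to 9 for FFVHC at 8 weeks. At 24 weeks they were 20 to 708, 0 to 0 and 1 to 25 in that order. The range was 63 to 246 for LF, 13 to 503 for HF, 640 to 1232 for FFHC and 358 to 1313 for FFVHC between SPF and GF mice at 8 weeks, and 18 to 314 for LF, 2958 to 5332 for HF, 907 to 2236 for FFHC and 386 to 2743 for FFVHC between SPF and GF mice at 24 weeks. Between SPF diets they were 0 to 0 for both pairs at 8 weeks. At 24 weeks they were 7 to 393 for FFHC against HF and 0 to 3 for FFVHC against FFHC. The range was 6551 to 7412 for SPF and 3172 to 4266 for GF between 24 and 8 weeks, and 218 to 828 for HF, 0 to 0 for FFHC and 0 to 1 for FFVHC in the interaction with time.

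Of 211 named values, 14 lost their call without the filter, 52 with the compared groups alone (0 gained it), 23 with the set of 8 libraries as a covariate, 0 with halved counts and 0 with DESeq2's size factors. With DESeq2 2 lost it, 6 gained it and 5 had no adjusted p, and with the clock covariate 10 of 57 lost it. Of 2795 values with 1 library left out 282 lost and 20 gained the call. Over genes with a mean of at least 2 CPM the correlation of the SPF and GF effects of FFVHC at 8 weeks was 0.17 in place of 0.07, and the other 5 stayed within the jackknife error, as all 6 did under the other alternatives, although that of FFHC at 24 weeks lay at 0.02 with the covariate and at -0.03 as reported. These correlations ran, over the libraries left out in turn, from 0.02 to 0.17 for HF, 0.05 to 0.14 for FFHC and 0 to 0.14 for FFVHC at 8 weeks. At 24 weeks they ran from 0.13 to 0.45 for HF, -0.16 to 0.16 for FFHC and -0.22 to 0.26 for FFVHC. At the lowest total, 24264151 counts, the gene floor of 3 counts is 0.124 CPM, so changes in genes below that level were not detectable. No paired analysis was possible because the replicate numbers only count the libraries of a group and link none across groups.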

Other observations

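Other gene groups also moved in the SPF HF livers of 24 weeks. All 7 MHC class II genes rose, also when adjusted over the list alone, such as H2-DMb1 (3.15-fold) and H2-Aa (3.33-fold). Of 9 cholangiocyte genes 7 rose (also 7 adjusted over the list alone), among them the ductal transcription factor gene Sox9 (3.95-fold) and the adhesion molecule gene Epcam (4.36-fold). Without HF replicate 4 Sox9 had a log2 fold change of 0.96, against 1.98 with it. Of 16 cell cycle genes 12 rose (13 adjusted over the list alone), such as the topoisomerase gene Top2a (3.74-fold), although replicate 4 had the lowest cell cycle score of the 6 and 7 passed without any 1 of LF replicates 2, 5 or 6 or HF replicates 3, 5 or 6. Of 14 male-biased genes 9 fell (10 adjusted over the list alone), Mup21, Mup3 and Hsd3b5 with log2 fold changes of -2.52, -1.94 and -7.54 (Hsd3b5 -6.86 without LF replicate 5), and of 20 lipogenesis genes 6 fell (also 6 adjusted over the list alone), such as the acetyl-CoA synthetase gene Acss2 (-2.30 ± 0.37). In order, camera gave adjusted p = 0.000394, 0.000461, 0.00128, 4.03e-06 and 9.3e-06, and adjusted p = 0.379, 0.226, 0.454, 0.246 and 0.379 with an estimated correlation. Several cytochrome P450 genes of the xenobiotic list fell as well, Cyp2c54, Cyp2c29 and Cyp2c37 with -3.52, -2.23 and -2.57 (paralogs may share their reads), while Cyp1b1 (chosen after its values were seen) rose 4.73-fold. Of that list's 25 genes 4 rose and 7 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.0204, and adjusted p = 0.397 with an estimated correlation).

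Lymphocyte genes were higher in SPF livers at 24 than at 8 weeks. Of 15 T and NK cell genes 13 rose and 1 fell (the same numbers adjusted over the list alone), such as the co-receptor genes Cd8a (5.57-fold) and Cd8b1 (3.17-fold) and the granzyme gene Gzmb (2.55-fold). Of 10 B and plasma cell genes 7 rose (8 adjusted over the list alone), led by the immunoglobulin genes Ighm (2.66-fold), Igkc (2.87-fold) and Igha (3.54-fold). All 7 MHC class II genes and 15 of 18 interferon response genes rose, also when adjusted over the lists alone, such as H2-Ab1 (2.62-fold) and Ifi27l2a (2.53-fold). In the same order camera gave adjusted p = 0.000936, 0.00891, 1.97e-05 and 5.9e-06, and adjusted p = 0.317, 0.339, 0.25 and 0.225 with an estimated correlation. In the same comparison 9 of 11 hepatocyte genes fell (10 adjusted over the list alone), with a median log2 fold change of -0.42, as did 7 of 10 mitochondrially encoded genes, while 7 of 9 cholangiocyte genes and 8 of 10 neutrophil genes rose (7, 7 and 9 adjusted over the lists alone). Camera gave these 4 adjusted p = 0.000116, 0.00714, 0.000105 and 0.000232, and adjusted p = 0.162, 0.439, 0.162 and 0.288 with an estimated correlation, and whether the shares of cells or the levels within cells changed was not tested. On HF at 24 weeks 4 of 5 erythroid genes were lower in SPF than in GF livers (5 adjusted over the list alone), Hbb-bt and Hbb-bs at -1.62 and -1.62 (camera adjusted p = 0.0276, and adjusted p = 0.48 with an estimated correlation). Without GF HF replicate 2 both lost the call, with log2 fold changes of -0.22 and -0.28, and 0 erythroid genes passed.

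Other splits of the libraries were counted for the remaining comparisons as well, all of them or 100 drawn, on fits of the compared groups alone, so that some real counts differ from those of the reported fit. For the diets against LF in SPF mice the share of splits with as many genes was under 0.05 for FFVHC at 8 weeks (210 genes, highest other 12, 1 of 35). At 24 weeks it was too for HF (2968, 169, 1 of 100) and FFHC (2355, 1158, 1 of 100). It was not for HF at 8 weeks (1, 28, 4 of 35). Shares are unadjusted and take libraries as exchangeable. Where the real count is 0 every split gives as many, so nothing about chance follows, also not for the genes called by the reported fit. That holds for FFHC at 8 weeks (highest other 3, 35 of 35 splits) and FFVHC at 24 weeks (highest other 5, 100 of 100). In GF mice of 8 weeks 10 splits are too few for a share under 0.05, with 0, 0 and 8 genes for HF, FFHC and FFVHC, highest others of 0, 9 and 4, and 10, 10 and 1 splits as large. In GF mice of 24 weeks HF, FFHC and FFVHC gave 0 genes each (highest others 1, 73 and 22, with 56 of 56, 56 of 56 and 100 of 100 splits), so again nothing follows.

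Between SPF and GF mice of 8 weeks the share was under 0.05 on LF (508 genes, highest other 21), FFHC (1167, highest other 1) and FFVHC (1127, highest other 1), each with 1 of 35 splits. It was not on HF (173, highest other 253, 2 of 35 splits). At 24 weeks it was under 0.05 on all 4 diets: LF (131, highest other 62, 1 of 100 splits), HF (1011, highest other 1415, 2 of 84), FFHC (3063, highest other 1, 1 of 84) and FFVHC (83, highest other 1576, 2 of 100). The 1576 genes, several times the real count, point to a structure of the samples besides housing. With 0 genes the splits decide nothing between SPF diets, with highest others of 1 and 0 at 8 weeks (35 of 35 splits) and of 2 and 0 at 24 weeks (100 of 100). Between 24 and 8 weeks the share was under 0.05 in SPF (7359, highest other 17) and GF livers (3075, highest other 5), each with 1 of 100 splits. For the interactions the splits carry the difference of housing or of time itself and decide nothing about chance. The real counts with housing were 6 for FFHC at 24 weeks (highest other 2440, 2 of 100 splits) and 0 for HF and FFVHC at 8 weeks (highest others 982 and 6, 100 of 100), and with time 1 for FFHC and 0 for FFVHC (highest others 2927 and 64, 8 and 100 of 100).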
